A study of Mus musculus with 9 samples.

How the data were processed

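The 9 arrays are 1-colour Affymetrix mouse gene arrays hybridised with total RNA labelled as sense-strand target, per the labels' protocols, 3 for each of wild-type, CD69-/- and CD69-activated wild-type CD4-enriched spleen T cells. Cells were cultured for 72 h with anti-CD3 and anti-CD28 beads, and the anti-CD69 and cross-linking antibodies were each used at a dilution of 1 in 200. The deposited values are log2 expression values made by the authors with RMA from the oligo package in R 2.12.1, per the submitters' processing notes. RMA ordinarily corrects background, quantile-normalizes and summarizes probes by median polish, and its settings and annotation are not given in the sources used here. Quantile normalization assumes similar distributions between arrays, and RMA compresses large fold changes. The values carry no detection call, so the levels of Y-linked genes in arrays with a female pattern (means of 4.33 for Eif2s3y, 5.06 for Uty and 5.16 for Kdm5d in wild type) show the level of a gene without a template.

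The table holds 35556 probe sets. The platform annotation gave 1 gene symbol for 21789 of them, several for 1621 and none for 12146. Of those with 1 symbol 21698 were matched by gene ID to the RefSeq gene table, whose chromosomes and gene order were used only for names, neighbours and nesting of genes, and no coordinates are given because the build of the annotation is not named. The brightest probe set over all arrays stood for each gene (999 genes had more than 1), which gave 19938 genes.

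Values were fitted as deposited with limma 3.58.1 in R 4.3.3 (lmFit, 3 group means over all 9 arrays, eBayes without trend; 6 residual and 4.78 prior degrees of freedom). The comparisons were CD69-/- minus wild type, CD69-activated minus wild type and CD69-activated minus CD69-/-. Tests were two-sided, and an adjusted p (Benjamini-Hochberg over all genes) under 0.05 was called. Fold changes are differences of log2 means. Gene lists (19) and cell type marker sets (10) were written before the data were examined, as were the comparisons, the tests, the naming rule and all alternatives except the exclusion of X and Y chromosome genes. Lists with at least 5 measured genes, 27 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. CD8 and gamma-delta T cell markers had too few measured genes. Counts adjusted over the list alone apply the adjustment to a list's own genes.

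Named genes were Cd69, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, leaving out predicted or clone-named genes and antigen receptor segments, and up to 4 called members of each list with the largest change. Some symbols from outside this rule are named as such, and Il1a, Sox13 and Cd163l1 are also from outside it. Genes with opposite effects were counted among genes called in both comparisons with wild type, beside the overlap of independent lists and 100 simulations of unchanged groups that share the wild-type arrays.

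The procedure was tested on simulated data for 19938 genes, made from the wild-type means and independent normal noise with each gene's residual SD. Genes therefore did not move together as in the real data, and only 50 genes were changed at each fold. The rates below may be better than those in the real data. In the simulated CD69-/- comparison 64% of genes changed 1.2-fold, 98% of those changed 1.5-fold and 100% of those changed 2-fold were called, and in the simulated activation comparison 52%, 94% and 100%. Of 19738 unchanged genes 6 were called in each. Alternatives were median centring, cyclic loess, leaving out the dimmest genes, testing all probe sets, averaging a gene's probe sets, fitting only the arrays compared, an intensity trend with a robust prior, array weights, a replicate block, a 1.5-fold minimum, an estimated inter-gene correlation, fry, leaving out each array and leaving out X and Y chromosome genes. Permutation tests in the closing section used 100000 permutations, and random lists numbered 10000. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.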

Results

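Gene expression was measured in CD4-enriched T cells from mouse spleen after 72 h of culture with beads carrying anti-CD3 and anti-CD28 antibodies. These antibodies act on the T cell receptor complex and the costimulatory receptor CD28. CD69 is a lectin-like membrane protein that appears on lymphocytes soon after activation and acts against the egress receptor S1P1. The 9 arrays formed 3 groups of 3: wild-type cells, CD69-/- cells, and wild-type cells to which an anti-CD69 antibody was added at 24 h and a cross-linking secondary antibody at 48 h, called CD69-activated below. The series asks which genes depend on CD69 in activated CD4 T cells. The labels call the samples biological replicates and do not say whether each came from its own mouse, so p-values measure the spread between these samples. They describe no culture with an isotype or secondary antibody alone, so effects of the antibodies and of CD69 ligation were not separated. Values are log2 RMA values with medians of 7.40 to 7.56 per array, and the number of arrays limits the precision. Arrays of one group correlated at 0.996 to 0.998 across probe sets, and arrays of different groups at 0.984 to 0.996.

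Cd69 itself was lower in every CD69-/- array. Its log2 level was 12.03, 12.12 and 12.37 in wild type, 9.65, 9.49 and 9.63 in CD69-/- and 11.80, 11.84 and 11.74 in CD69-activated cells. The CD69-/- mean was 5.99-fold lower than wild type (log2 fold change -2.58, SE 0.078, adjusted p = 1.22e-08, n = 3 per group). The remaining CD69-/- level lay above the array medians, and whether the probes of this probe set lie inside the deleted part is not given in the sources used here. In CD69-activated cells Cd69 fell by 0.38 (adjusted p = 0.00512). Sex-linked genes separated the same arrays. Xist, the X-inactivation transcript of female cells, had a mean of 12.59 in wild type, 12.95 in CD69-activated and 6.01 in CD69-/- arrays. The Y-linked genes Eif2s3y, Uty and Kdm5d had means of 9.78, 9.54 and 8.83 in CD69-/- arrays and of 4.33, 5.06 and 5.16 in wild type. The CD69-/- arrays thus carried a male pattern and the other 6 a female pattern, and sex and genotype coincided in every comparison with CD69-/-. The labels name the wild-type and the CD69-/- cells as B6.

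**Figure D1:**
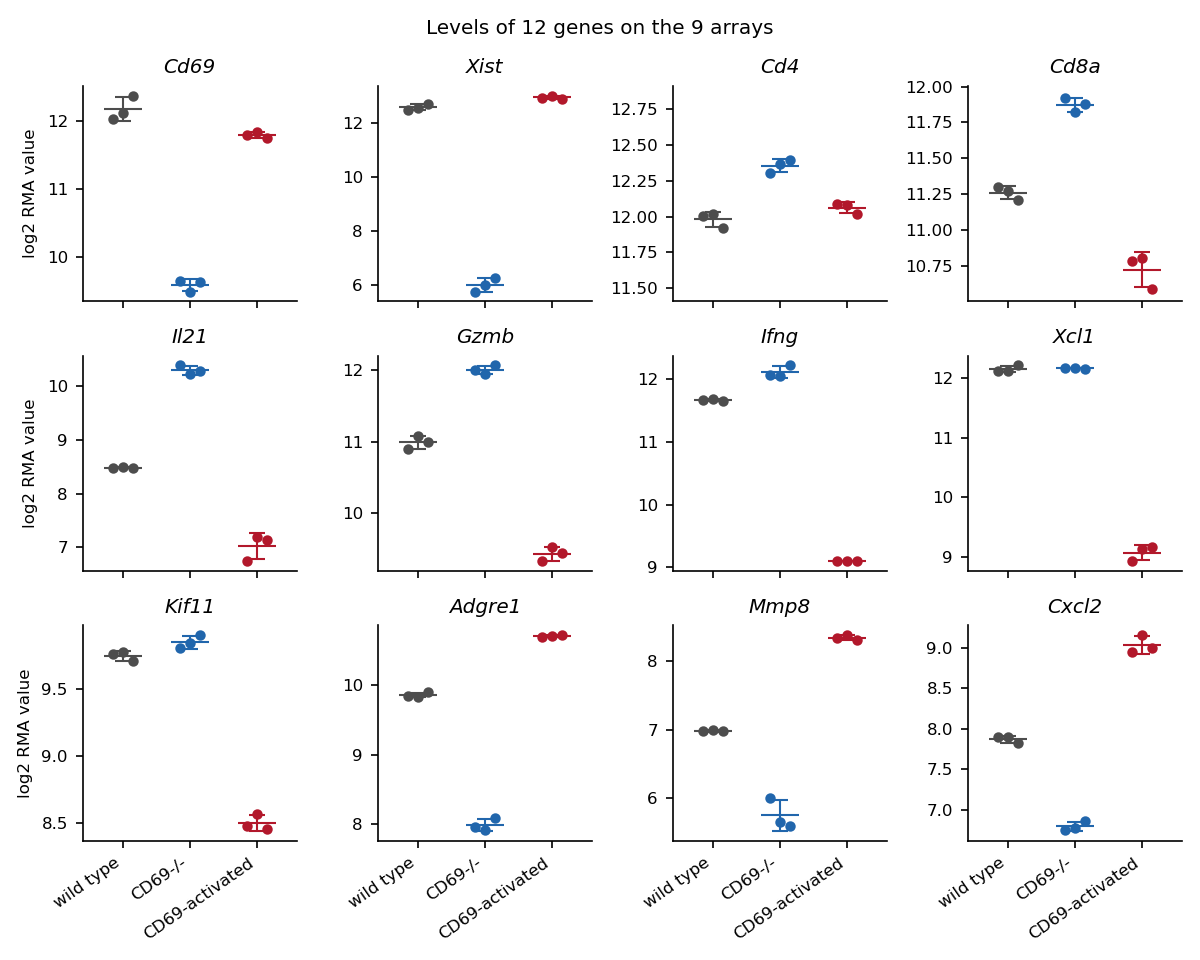
Log2 RMA values of 12 genes (vertical axes, a separate scale for each gene) on the 9 arrays, with 1 point per array, a wide bar at the group mean and whiskers of 1 SD (n = 3). Cd69 and Xist are low in CD69-/- arrays, Il21 and Gzmb are highest in CD69-/- and lowest in CD69-activated arrays, and Adgre1, Mmp8 and Cxcl2 show the opposite order.

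Without CD69, effector T cell genes were higher and genes of B cells and myeloid cells were lower. Il21, a cytokine of helper T cells, rose 3.51-fold (log2 fold change 1.81, SE 0.095, adjusted p = 8.23e-07, n = 3 per group) and Gzmb, a granzyme of cytotoxic cells, rose 2.01-fold (1.01, SE 0.061, adjusted p = 1.83e-06). Il10, an inhibitory cytokine, rose by 0.94. Adgre1, which encodes a surface marker of macrophages, fell by 1.86 and Clec7a, a receptor for fungal glucans, fell by 1.19. Limma called 3018 of 19938 genes, 1667 higher and 1351 lower, of which 81 rose and 149 fell by at least 1.5-fold. With the arrays centred on their medians the calls were 2462 higher and 886 lower, and after cyclic loess 1627 higher and 1333 lower. Standard errors of the named log2 fold changes in this comparison lay between 0.033 and 0.14.

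Apart from sex-linked genes and Cd69, the largest rises after Il21 were those of Ctla2a (1.16), the peptide transporter Slc15a2 (1.14), Gzmb (1.01), the BMP receptor Bmpr1a (0.99) and Igfbp4 (0.98). The largest falls were those of Car1, a carbonic anhydrase of red cells (-2.35), Klrb1b (-2.08), Adgre1, Ifi208 (-1.77), the macrophage elastase Mmp12 (-1.49), Iltifb (-1.41) and the neutrophil collagenase Mmp8 (-1.23). Iltifb, a near-identical copy of Il22, and Klrb1b, from a family of similar receptors, are uncertain at the level of the single gene.

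Effector and activation lists moved up in CD69-/- cells together with CD4 T cell markers, whose median was 0.42, and with the CD8 genes Cd8a (0.61) and Cd8b1 (0.43). Of the 25 measured Th1 and cytotoxic genes, 19 rose, 1 fell and 5 did not pass (20 and 1 adjusted over the list alone; median 0.43, camera adjusted p = 3.61e-17). Gzmb, Il18r1 (0.77), Ccl4 (0.76) and Tnf (0.67) led it. The IL-2 and STAT5 list had 19 of 23 members higher and 1 lower (19 and 1 adjusted over the list alone; median 0.28, adjusted p = 8.32e-15), with Cish at 0.54 and Il2rb at 0.52. Both calls held with an estimated correlation between genes. T cell receptor response genes rose in 23 of 37 cases and fell in 2 (24 and 4 adjusted over the list alone), with Cd28, also a CD4 T cell marker here, at 0.62 and Il2 at 0.61. That list's call was lost at an adjusted p = 0.0651 with an estimated correlation. Regulatory T cell genes rose in 16 of 26 cases and fell in 5 (18 and 5 adjusted over the list alone), with Izumo1r at 0.62 and Ctla4 at 0.59, and adjusted p = 0.0918 with an estimated correlation. Inhibitory receptors rose in 12 of 19 cases and fell in 3 (13 and 3 adjusted over the list alone), with Lag3 at 0.78 and Havcr2, encoding TIM-3, at 0.71, and adjusted p = 0.0551 with an estimated correlation.

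Lists of other helper subsets were mixed. Of 16 follicular helper genes 7 rose and 3 fell (8 and 3 adjusted over the list alone; median 0.12, camera adjusted p = 0.00202, and adjusted p = 0.233 with an estimated correlation), with Icos at 0.56. Of 18 Th2 genes 7 rose and 2 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.0466, and adjusted p = 0.340 with an estimated correlation), with Il10 and Ccr8 (0.76) higher and Il9 (-0.98) lower. The Th2 call was also lost with median centring (0.112), without wild-type replicate 2 (0.0531) or 3 (0.102) and without CD69-/- replicate 3 (0.0541). The 19 memory, naive and circulation genes had 10 higher and 5 lower (10 and 7 adjusted over the list alone; adjusted p = 0.0128, and adjusted p = 0.351 with an estimated correlation). That call was lost with median centring (0.0691), after cyclic loess (0.0555) and without the dimmest genes (0.0855) too. Igfbp4 and Cd27 (0.52) rose and Klf2, a regulator of T cell egress, fell by 0.54. The Th17 list did not pass (adjusted p = 0.639). Its median was -0.091 and its mean 0.079, with 8 members higher and 9 lower over all genes and over the list alone, and Ccr6 at -0.77. The TGF-beta list had 10 of 33 members higher and 3 lower (11 and 5 adjusted over the list alone) and did not pass (adjusted p = 0.0564), but passed without wild-type replicate 1 (0.0481) or CD69-/- replicate 2 (0.0399), with all probe sets (0.0281) and in fry (0.0155). Pmepa1, a TGF-beta target, was at 0.57. The interferon list had 9 of 48 members higher and 13 lower (12 and 13 adjusted over the list alone; adjusted p = 0.984), with a median of -0.00062, a mean of -0.0032 and a test direction of up. Chemokines and their receptors split 12 higher and 13 lower of 38 (12 and 17 adjusted over the list alone; adjusted p = 0.439). Cxcl2, a neutrophil chemokine, was at -1.07 and Cxcl3 at -0.81.

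Markers of other cell types fell and T cell markers rose. All 18 B cell markers fell (18 also adjusted over the list alone; median -0.44, camera adjusted p = 2.08e-22), with the IgE receptor Fcer2a at -0.97 and Siglecg at -0.71. B cell genes were bright in all groups: Cd79b, named after its values were seen, had a mean of 13.61 in wild type and 13.36 in CD69-/- cells. Of 27 markers of monocytes, macrophages and dendritic cells 21 fell and none rose (25 fell adjusted over the list alone; median -0.32, adjusted p = 9.78e-21). NK cell markers fell in 7 of 11 cases and rose in 1 (7 and 2 adjusted over the list alone; median -0.42), neutrophil and mast cell markers fell in 6 of 18 and rose in 1 (8 and 1; median -0.13), and erythroid markers fell in 5 of 9 and rose in 1 (5 and 1; median -0.19). These calls held with an estimated correlation. The NK marker that rose was Prf1 (0.53), which also belongs to the Th1 and cytotoxic list. Plasma cell markers fell in 5 of 8 cases and rose in 1, with the same counts adjusted over the list alone (median -0.24, adjusted p = 0.0651 with an estimated correlation). Platelet markers fell in 4 of 6, also adjusted over the list alone (median -0.23, adjusted p = 0.0631 with an estimated correlation). CD4 T cell markers rose in 11 of 12 cases, also adjusted over the list alone (median 0.42, adjusted p = 6.10e-16, held with an estimated correlation), with Thy1 at 0.60 and Cd3d at 0.58. Cd8a and Cd8b1 rose too, by 0.61 and 0.43. Of 3 gamma-delta T cell markers measured, Blk was at -0.52, Sox13 at -0.057 and Cd163l1 at -0.033, and only Blk passed.

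Cell cycle genes moved little between CD69-/- and wild-type cells. The G2/M list had 2 of 29 members lower and none higher, also adjusted over the list alone (median -0.020, adjusted p = 0.436). The G1/S list had 4 of 29 higher and 1 lower (5 and 1 adjusted over the list alone; median 0.097, camera adjusted p = 0.000729, and adjusted p = 0.351 with an estimated correlation). Glycolysis and hypoxia genes rose in 20 of 36 cases and fell in 4 (22 and 6 adjusted over the list alone; median 0.19, adjusted p = 0.190 with an estimated correlation), with the prolyl hydroxylase Egln3 at 0.73 and the glycolytic enzyme Tpi1 at 0.47. Sterol synthesis genes fell in 9 of 23 cases and none rose (10 lower adjusted over the list alone; median -0.066, adjusted p = 0.405 with an estimated correlation), with the desaturase Scd1 at -0.79. The amino acid and unfolded protein response list had 11 of 31 higher and 3 lower (12 and 3 adjusted over the list alone; adjusted p = 0.405 with an estimated correlation), with Trib3 at 0.35 and the cystine transporter Slc7a11 at -0.90. The apoptosis and p53 list had 8 of 26 higher and 3 lower (9 and 3 adjusted over the list alone; adjusted p = 0.285 with an estimated correlation), with Tnfrsf10b at 0.52, and its call was also lost after cyclic loess (0.0981) and without the dimmest genes (0.102).

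Lectin-like genes that neighbour Cd69 in the natural killer gene complex were lower as a list in CD69-/- cells. Including Cd69, 15 of 41 fell and 6 rose (16 and 8 adjusted over the list alone; median -0.10, camera adjusted p = 0.000451, held with an estimated correlation). The fall of Cd69, the deleted gene, was fixed by the design and adds to this call, and the list was not tested without it. After Cd69, Klrb1b, Clec7a and Clec2i (-0.97) led the falls, and Clec7a is also one of the myeloid markers. NK cell markers, several of which belong to this complex, moved with it (median -0.42).

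**Figure D2:**
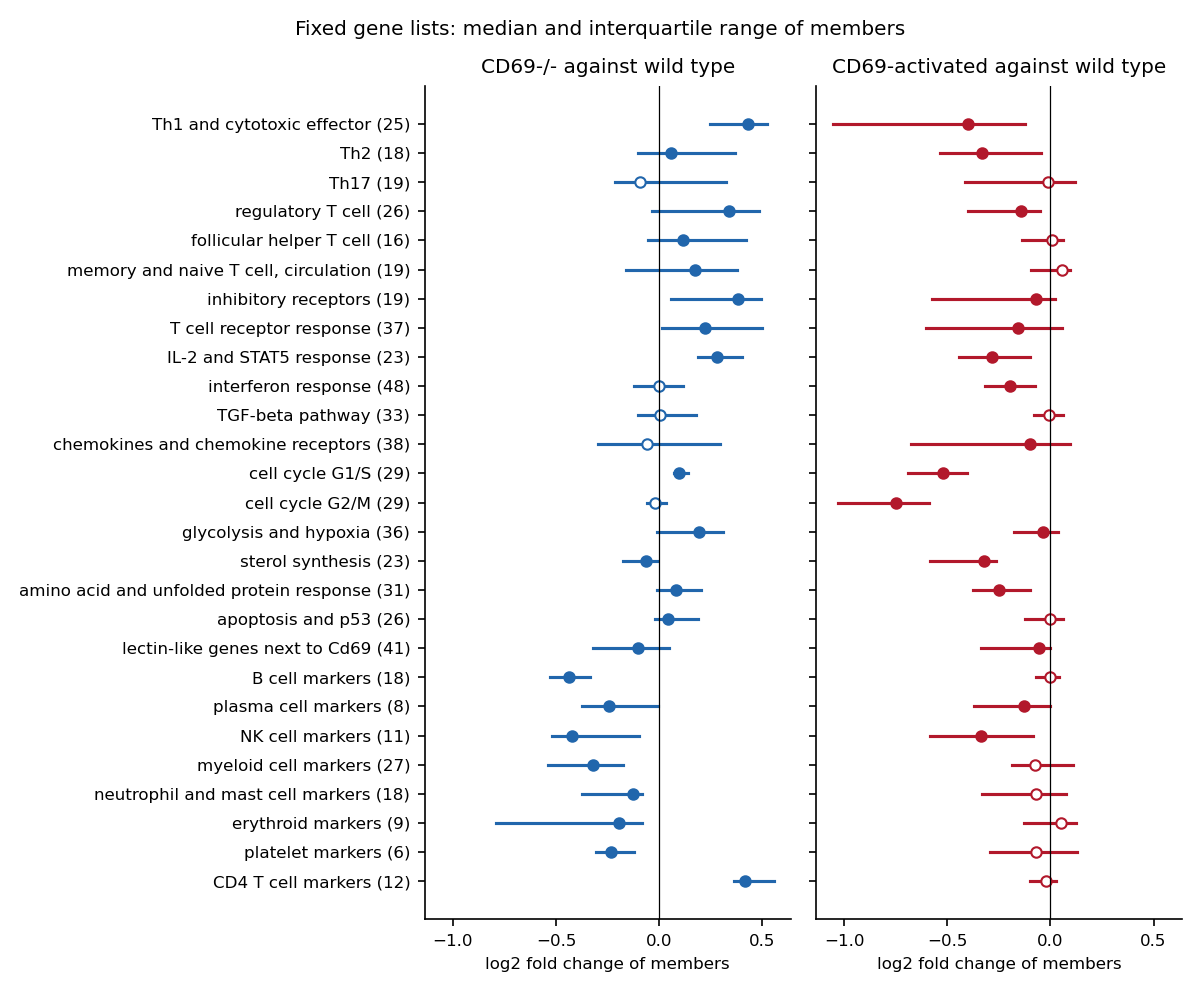
Median (circle) and interquartile range (line) of the log2 fold changes of the measured members of 27 fixed gene lists, for CD69-/- (left) and CD69-activated (right) against wild type. The number of members is in parentheses, and filled circles mark lists past an adjusted p of 0.05 in camera with the preset correlation. Cell cycle lists lie far below 0 only on the right (medians -0.52 and -0.75), and B cell markers only on the left (median -0.44).

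After CD69 activation, Ifng, Gzmb and cell cycle genes were lower than in wild-type cells without the antibodies, while Cxcl2 and Il1a were higher. Xcl1, a chemokine for cross-presenting dendritic cells, was 8.44-fold lower (log2 fold change -3.08, SE 0.058, adjusted p = 2.08e-10, n = 3 per group) and Ifng, encoding interferon gamma, was 5.92-fold lower (-2.57, SE 0.045, adjusted p = 1.95e-10). The mitotic kinesin Kif11 fell by 1.25 and Top2a, a DNA topoisomerase of dividing cells, fell by 1.21. Limma called 4742 of 19938 genes, 2015 higher and 2727 lower, of which 56 rose and 260 fell by at least 1.5-fold. With the arrays centred on their medians the calls were 764 higher and 4741 lower, and after cyclic loess 1973 higher and 2802 lower. Standard errors of the named log2 fold changes lay between 0.033 and 0.21.

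Besides Xcl1 and Ifng, the largest falls were those of Penk, the proenkephalin gene (-2.11), the signalling regulator Rgs16 (-1.98), the chemokine gene Cxcl9 (-1.90), Car1 (-1.88), the immediate early gene Nr4a2 (-1.85), Gzma (-1.63), Crtam (-1.57) and Gzmb (-1.56). The largest rises were those of Phxr4 (2.01), the receptor gene Gpr52 (1.70), the miRNA locus Mir505 (1.61), Mmp8 (1.35), Gpr21 (1.28), Mir687, Cxcl2 (1.16), Pou5f2 (1.14), Mir128-1 (1.12) and Insyn2b (1.12). A probe set of a miRNA gene measures its locus or precursor, not a mature arm.

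Both cell cycle lists fell. All 29 measured G2/M genes fell, also adjusted over the list alone (median -0.75, camera adjusted p = 8.70e-32), and the call held at an adjusted p = 0.0429 with an estimated correlation. Bub1 was at -1.20 and Ccna2 at -1.18. Of 29 G1/S genes 27 fell and none rose (29 fell adjusted over the list alone; median -0.52, adjusted p = 4.39e-25, and adjusted p = 0.0527 with an estimated correlation). The ribonucleotide reductase gene Rrm2 fell by 1.35 and Uhrf1 by 1.11. CD4 T cell markers had a median of -0.020 and Cd8a fell by 0.54.

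Effector lists fell beside a fall of Cd8a and Cd8b1 (-0.25) and of NK cell markers (median -0.34). The NK set and the Th1 and cytotoxic list share Gzma and Prf1, so their falls are not independent. Of 25 Th1 and cytotoxic genes 19 fell and 1 rose (20 and 2 adjusted over the list alone; median -0.40, camera adjusted p = 1.16e-14, and adjusted p = 0.0504 with an estimated correlation). Of 18 Th2 genes 10 fell and none rose (12 and 1 adjusted over the list alone; median -0.33, adjusted p = 0.0635 with an estimated correlation), with Penk, Il9 (-1.09) and Ccr8 (-0.73) leading. The IL-2 and STAT5 list had 15 of 23 lower and none higher (17 and 1 adjusted over the list alone; median -0.28, adjusted p = 0.0704 with an estimated correlation), with Socs2 at -1.31, Myc at -0.81 and the IL-2 receptor chain Il2ra at -0.76. T cell receptor response genes fell in 18 of 37 cases and rose in 4 (19 and 4 adjusted over the list alone; median -0.16, adjusted p = 0.134 with an estimated correlation), with Nr4a2, Nr4a3 (-1.20) and Egr2 (-1.09) leading. Regulatory T cell genes fell in 12 of 26 cases and rose in 1, also adjusted over the list alone (median -0.14, adjusted p = 0.140 with an estimated correlation), while Foxp3, the lineage factor, named after its values were seen, was at -0.046 (adjusted p = 0.449). Inhibitory receptors fell in 7 of 19 cases and rose in 2 (8 and 2 adjusted over the list alone; adjusted p = 0.216 with an estimated correlation), with Havcr2 at -1.23 and Cd160 at -0.94. Chemokines and their receptors fell in 18 of 38 cases and rose in 5 (19 and 6 adjusted over the list alone; adjusted p = 0.209 with an estimated correlation), with Xcl1, Cxcl9 and Ccl22 (-1.43) lower and Cxcl2 higher.

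Interferon and biosynthetic lists fell as well. Of 48 interferon response genes 33 fell and 1 rose (34 and 1 adjusted over the list alone; median -0.20, camera adjusted p = 1.50e-12, and adjusted p = 0.0966 with an estimated correlation), with Cxcl10 at -1.12, Slfn5 at -0.96 and the antiviral sensor Oas2 at -0.63. Of 23 sterol synthesis genes 19 fell and none rose (20 fell adjusted over the list alone; median -0.32, adjusted p = 9.03e-15, and adjusted p = 0.0966 with an estimated correlation), with Idi1 at -1.11, Cyp51 at -0.88 and Sqle at -0.82. The amino acid and unfolded protein response list had 21 of 31 lower and 1 higher (22 and 2 adjusted over the list alone; median -0.25, adjusted p = 0.0976 with an estimated correlation), with Cth at -1.30 and the asparagine synthetase Asns at -1.19. Glycolysis and hypoxia genes fell in 10 of 36 cases and rose in 6 (11 and 7 adjusted over the list alone; camera adjusted p = 0.0401, and adjusted p = 0.595 with an estimated correlation), with Hk2 at -0.69. That last call was also lost with median centring (0.0779), after cyclic loess (0.403), without the dimmest genes (0.186), without X and Y chromosome genes (0.0846), without wild-type replicate 1 (0.107) or 2 (0.0521) and without CD69-activated replicate 1 (0.123).

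Markers of B cells and CD4 T cells did not pass as lists after CD69 activation. B cell markers had 4 of 18 higher and 2 lower, also adjusted over the list alone (median -0.0038, mean 0.018, adjusted p = 0.858), with Blk at 0.55 and Fcer2a at -0.41. CD4 T cell markers had 3 of 12 lower and none higher (3 and 1 adjusted over the list alone; adjusted p = 0.257), with Thy1 at -0.37. NK cell markers fell in 6 of 11 cases (7 adjusted over the list alone; camera adjusted p = 3.58e-06, held with an estimated correlation), led by Gzma, Ncr1 (-0.92) and the perforin gene Prf1 (-0.80). Of these, Gzma and Prf1 also belong to the Th1 and cytotoxic list. Plasma cell markers fell in 4 of 8 cases (4 lower and 1 higher adjusted over the list alone; adjusted p = 0.0104, and adjusted p = 0.0966 with an estimated correlation), with Jchain at -0.62, and the call was also lost without the dimmest genes (0.0502). Lectin-like genes next to Cd69 fell in 13 of 41 cases and rose in 1 (13 and 3 adjusted over the list alone; adjusted p = 0.0504 with an estimated correlation), with Klrc1 at -0.78 and Klrk1 at -0.73. Among the other lists without a call, myeloid markers had an adjusted p = 0.120, neutrophil and mast cell markers and the apoptosis list 0.257 each, platelet markers 0.323, erythroid markers 0.424, Th17 genes 0.167, follicular helper genes 0.305, TGF-beta genes 0.817 and memory, naive and circulation genes 0.858. Myeloid markers passed as lower with all probe sets (0.0199). In fry, which tests a list's own shift, the myeloid (0.0161), Th17, follicular helper, apoptosis, erythroid, platelet and CD4 T cell lists passed as lower. The median and the mean differed in sign for follicular helper genes (0.0071 and -0.13), memory genes (0.058 and -0.015) and erythroid markers (0.050 and -0.22). Single members of these lists still passed, such as Adgre1 at 0.85, Cd14 at 0.46 and Il21 at -1.46.

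CD69-activated and CD69-/- cells differed in more genes than either did from wild type, and their contrast also tests the difference between the effects of activation and of loss. Il21 was 9.69-fold lower in CD69-activated than in CD69-/- cells (log2 fold change -3.28, SE 0.095, adjusted p = 2.09e-09, n = 3 per group), Ifng was 8.08-fold lower (-3.01, adjusted p = 1.15e-11) and Gzmb 5.92-fold lower (-2.57, adjusted p = 4.10e-10). Adgre1 was higher by 2.71, Mmp8 by 2.58 and Cxcl2 by 2.23. Limma called 8501 genes, 4314 higher and 4187 lower, of which 275 rose and 526 fell by at least 1.5-fold. With the arrays centred on their medians, which moved the median of all genes by -0.13, the calls were 1354 higher and 7990 lower. After cyclic loess they were 3146 higher and 4359 lower. The direction of small changes in this comparison is thus relative to the scaling. The sex pattern differed between these groups too.

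Among the other named genes Xcl1 (-3.09), Penk (-2.46), Rgs16 (-2.44) and Havcr2 (-1.93) were lower and Mir505 (2.10), Klrb1b (1.90), Mmp12 (1.85), Gpr52 (1.83) and the circadian repressor Bhlhe41 (1.78) were higher in CD69-activated cells. Of 25 Th1 and cytotoxic genes 23 were lower, all 29 G2/M genes were lower, and 22 of 23 IL-2 and STAT5 genes were lower, with none higher in these lists and the same counts adjusted over the list alone. T cell receptor response genes were lower in 27 of 37 cases and higher in 3, also adjusted over the list alone (median -0.51), with Nr4a2 at -1.72 and Il2 at -1.64. Inhibitory receptors were lower in 16 of 19 cases and higher in 2 (16 and 3 adjusted over the list alone; median -0.47), with Cd160 and Lag3 at -1.40 each. All 18 B cell markers were higher, also adjusted over the list alone (median 0.41), and 11 of 12 CD4 T cell markers were lower (11 and 1 higher adjusted over the list alone; median -0.50), while Cd8a differed by -1.15. NK cell markers had a median of 0.17 and a mean of -0.14 (adjusted p = 0.548). Camera with the preset correlation called 19 of 27 lists, these among them except NK cell markers, and none of the 19 calls held with an estimated correlation (adjusted p from 0.0658 to 0.391). Fry called all 27. The calls of chemokines (0.229 with median centring), erythroid markers (0.0508 without X and Y chromosome genes) and platelet markers (0.0676 without CD69-/- replicate 2 and 0.0717 without CD69-activated replicate 2) were lost under those alternatives, and that of platelet markers also with all probe sets (0.0597). Calls of the apoptosis list and of neutrophil and mast cell markers, at 0.0502 and 0.0531, were gained under others, such as 0.0350 and 0.00703 with median centring, and those of Th17 and TGF-beta genes with all probe sets (0.0239 and 0.0198).

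**Figure D3:**
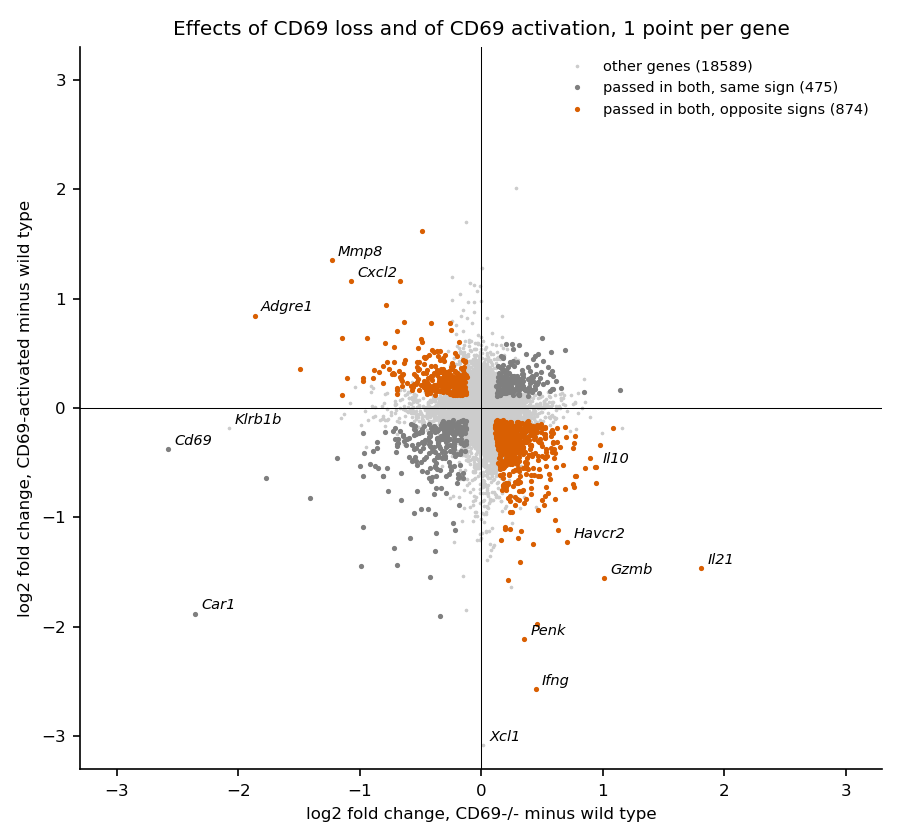
Log2 fold change of each gene in CD69-/- against wild type (horizontal axis) and in CD69-activated against wild type (vertical axis), with 1 point per gene. Orange points are the 874 genes that passed in both with opposite signs and dark grey points the 475 that passed with the same sign. The genes Xist, Eif2s3y, Uty and Kdm5d lie outside the axes.

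Genes that passed in both comparisons with wild type more often moved in opposite directions than in the same one. Of 1349 such genes 874 had opposite signs: 588 were higher in CD69-/- and lower on activation, against 228 for independent lists, and 286 were lower in CD69-/- and higher on activation, against 136.5 (137 after rounding). The same-sign genes were 198 higher in both, against 168, and 277 lower in both, against 185. Il21 (1.81 and -1.46), Gzmb (1.01 and -1.56), Havcr2 (0.71 and -1.23), Ccr8 (0.76 and -0.73), Ccl4 (0.76 and -0.70), Lag3 (0.78 and -0.62) and Cd8a (0.61 and -0.54) were higher in CD69-/- cells and lower after activation. Mmp8 (-1.23 and 1.35), Cxcl2 (-1.07 and 1.16), Adgre1 (-1.86 and 0.85), Lcn2 (-0.69 and 0.71) and Il1a (-0.94 and 0.64) moved the other way. The CD69-/- arrays also differed in sex pattern, and some of these genes mark other cell types, such as Cd8a and Adgre1. Opposite regulation by CD69 was thus not separated from sex or cell composition. Across genes, which are not independent replicates, the covariance of the fold changes was -0.0045, against a simulated median of 0.0014 (range -0.0019 to 0.0083) for unchanged groups measured against the same wild-type arrays. The difference was -0.0059. Pearson's r was -0.14, against a simulated 0.55 (range -0.66 to 0.94), and Spearman's rho was -0.20. Both effects were measured against the same 3 wild-type arrays, which could not be split. A simulated median of 0 genes had opposite signs, as an adjusted threshold makes likely for unchanged groups. The number of genes changed in opposite directions by CD69 loss and CD69 activation was 560 without wild-type replicate 2, 536 without wild-type replicate 3 and 1353 with median centring.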

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

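The exclusion of X and Y chromosome genes was chosen after the data were seen, and all other alternatives before. Single genes were followed under the other scalings, filters, summaries and fits and with each array left out, not under the 1.5-fold minimum. Under these the Cd69 difference kept its direction and its call in all 3 comparisons. Of 335 pairs of a named gene and a comparison, leaving out Cd69 in CD69-/- against wild type, 316 kept both wherever the gene was tested. The call was lost under at least 1 alternative in 19 pairs, and 0 turned. With an estimated inter-gene correlation, the lists called were 9 (CD69-/- against wild type), 2 (CD69-activated against wild type) and 0 (CD69-activated against CD69-/-), in place of 22, 16 and 19, and fry called 21, 23 and 27. A 1.5-fold minimum left 230, 316 and 801 genes, by its construction. Testing all 35556 probe sets in place of 19938 genes gave 2876 calls for CD69-/- against wild type, 7222 for activation against wild type and 12931 for activation against CD69-/-. Of these calls, 242 higher and 344 lower, 2039 higher and 727 lower, and 3459 higher and 1252 lower were probe sets without 1 gene name. Other reasons for the change in counts were not tested. The number of genes changed in opposite directions by CD69 loss and CD69 activation was 1353 with median centring and 536 to 904 with 1 array left out, the lowest without wild-type replicate 3 and 560 without wild-type replicate 2; the cause was not tested. Median centring and cyclic loess turned the direction of 0 called lists. Without X and Y chromosome genes 2944, 4622 and 8250 genes were called, and 864 genes changed in opposite directions.

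Groups share replicate numbers 1 to 3 in the labels. Same-numbered arrays did not deviate together (correlations of residuals of 0.14, -0.027 and 0.074 between CD69-/- and wild type, and of -0.10, -0.0076 and -0.24 between CD69-activated and wild type), and 1 of 9 arrays correlated best with its own number. With the replicate block the fits called 2609, 4345 and 8055 genes, 22, 16 and 19 lists and 720 genes changed in opposite directions by CD69 loss and CD69 activation. Values near those of genes without a template, such as Y-linked genes in female-pattern arrays, limit what can be read from dim genes.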

Other observations

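All tests on cell composition, sex and the cell cycle here were chosen after the results they bear on were seen, as were the window around Cd69 and the count of unnamed probe sets, and the tests on nested genes and on other groupings of the arrays were written before their results were seen, except the adjustment for level. Genes named in this part other than Cd69, Xist, Cd8a, Klri2, Gpr21 and Mir128-1 were chosen after their values were seen. The 10 splits of 6 arrays are too few for a share under 0.05. The real grouping gave 3018, 4742 and 8501 genes and 22, 16 and 19 lists in the comparisons of CD69-/- with wild type, of CD69-activated with wild type and of CD69-activated with CD69-/-. The real split alone, 1 of 10, reached each of these counts. The highest counts in other splits were 0, 0 and 0 genes and 13, 14 and 16 lists. For genes with opposite effects, 1 of 100 groupings of the 9 arrays, the real one, gave 874, and the highest of the others gave 84. Other groupings mix arrays of groups that differ, which raises the spread within groups and lowers the calls. This share of under 0.05 sets the real grouping apart from random assignments, but does not test the opposite directions themselves.

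Genes next to Cd69 changed often in CD69-/- cells. Of the 50 nearest measured genes, 25 on each side in gene order, 21 passed, 13 lower and 8 higher, with a median absolute log2 fold change of 0.14. Of 19166 windows of this kind on the autosomes, which overlap, 0.047% held as many called genes and 0.047% had as large a median. Among them Klrb1f was at -0.80, Klri2 at -0.86, Klra6 at -0.66, Klrc3 at 0.69 and Klra5 at 0.78. These genes have near-identical relatives, so values of single members are uncertain. The values also do not separate an effect of CD69 loss from a difference in the DNA around the deleted gene, which was not tested. Probe sets without 1 gene name, 13767 in the fit of all probe sets, rose in 2039 cases and fell in 727 after CD69 activation (median 0.062), and rose in 242 and fell in 344 in CD69-/- cells (median -0.019). Median centring moved the median of all genes by -0.081 after activation, so the excess of rises is relative to the scaling. The median of the named genes was 0.017 in that comparison. A shift of whole arrays does not change the gap between these 2 medians.

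In CD69-/- arrays, most marker sets of other cells were lower and T cell markers higher. Fewer cells other than T cells in the CD69-/- cultures would lower their markers and raise those of CD4 and CD8 T cells. The falls need not be equal between cell types. Of 9 marker sets other than that of CD4 T cells 8 had negative medians, from -0.44 to -0.057. All 7 tested sets, those with at least 5 genes, were among them. CD8 T cell markers had a median of 0.52, beside 0.42 for CD4 T cell markers. The NK set holds genes of the complex next to Cd69, shares Tyrobp and Fcer1g with the myeloid set, and holds the cytotoxic genes Gzma and Prf1. The only called gamma-delta marker is also a B cell marker. The sets are therefore not independent. B cell and myeloid markers had medians of -0.44 and -0.32, and their means differed by -0.0039 (95% interval -0.16 to 0.17, permutation p = 0.971; over the 7 sets with at least 5 genes permutation p = 0.455). Because equal falls are not required, this comparison could not exclude fewer other cells. The directions of most marker sets are those that fewer non-T cells would give, so this explanation stays open. The medians of B cell and T cell markers together would need 56.2% of the wild-type RNA to come from other cells, in cultures labelled as CD4-enriched. The bright B cell genes Cd74 (13.57 in wild type), Cd79b (13.61) and Ighm (11.47) fell by only 0.20, 0.26 and 0.17. They were chosen after their values were seen, while all 18 markers of the fixed B cell list fell (quartiles -0.53 and -0.33). Whether their brightness limited the measured fall was not tested. Male mice as the source of the CD69-/- cells (Xist at -6.57) cannot be told apart from genotype, since sex and genotype coincide in all 9 arrays. An effect of CD69 loss inside T cells, the biological explanation the design names, stays open beside both and was not tested apart from them.

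After CD69 activation cell cycle genes were lower. A compressed signal range of the CD69-activated arrays would move other genes of the same brightness alike, but 0% of 10000 brightness-matched lists had a median as low as that of the G2/M list (-0.75; matched medians from -0.080 to 0.051 over the middle 95%). Fewer CD8 T cells would allow a fall no larger than that of Cd8a (-0.54, SE 0.057), if Cd8a tracks them. The interval of the G2/M median (-0.91 to -0.68) lies below it, and 22 of 29 G2/M genes fell by more than Cd8a. Fewer T cells among the cultured cells would lower T cell markers, whose median was -0.020 (interval -0.11 to 0.041). Both intervals resample the genes of a list, which move together (estimated correlations of 0.19 for G2/M genes and 0.29 for T cell markers). They leave out the spread between arrays and may be too narrow. A lower share of dividing cells after CD69 ligation may account for the pattern, as a hypothesis from the same data that was not itself tested. Antibody effects stay open because no isotype culture is described.

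Several genes inside the span of another gene rose after CD69 activation, such as Gpr21 inside Rabgap1 (1.28, host 0.11), Mir128-1 inside R3hdm1 (1.12, host 0.015) and Mir103-2 inside Pank2 (1.04, host -0.018). More signal on all dim probe sets, as genomic DNA would give, predicts no difference by host. Dim genes inside a bright host rose by 0.052 more than those inside a dim host (95% interval 0.024 to 0.089, permutation p = 1e-05, the smallest 100000 permutations can give). This met the rule written beforehand against that explanation, a difference over 0.05 with a permutation p under 0.05. The interval reaches below 0.05, however, so the explanation was left open. More unspliced RNA of expressed host genes predicts such a difference also for genes that are not miRNA genes. Without miRNA genes the difference was 0.035 (permutation p = 0.00221; 141 and 178 genes), and 0.040 after the change of unnested genes at the same level was taken off, while the hosts had a median change of 0.0091. These values meet what unspliced RNA predicts, so it may contribute to the pattern, while signal on all dim probe sets stays open beside it, and genes that share a host are not independent.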
